A study of Homo sapiens and Bos taurus and Rattus norvegicus with 12 samples.

How the data were processed

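Total RNA of 12 samples was hybridised to Affymetrix arrays of 3 platforms, 8 for human H295R cells, 2 for bovine and 2 for rat glomerulosa cells. The deposited value tables hold probe set intensity on a linear scale. The submitters' processing notes name RMA, with no version, but RMA as usually run gives log2 values with equal distributions, and these intensities are linear and differ in distribution between arrays, so the step that made them is not given in the sources used here. The authors also deposited 1 table per species with a scaled signal for each group and, per the file headers, probe sets flagged present in both arrays; the flagging software is not given in the sources used here. In those tables the authors' signal equalled the intensity divided by the median of its array, averaged over the 3 arrays of a group for H295R (largest log2 gap 8.4e-06), and the ratio is AngII over control, per the file headers. Of value columns in the value tables, 0 matched no sample.

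Genes were named from the authors' deposited tables, which listed 21432 human, 13568 bovine and 15103 rat probe sets. Names were updated through a table of human RefSeq genes (GRCh38.p14). Probe sets with 1 name numbered 18071, 4710 and 7554. Of these, 2903 bovine and 1291 rat probe sets had no symbol and were named by a match of their description to that of a single gene, a step chosen after the data were seen. For each gene the probe set with the highest mean over the arrays of its platform was used, and control probe sets were left out. Where another probe set of a gene whose AngII change is printed differed from it by over 1.5 times, that value is given too, a comparison chosen after the data were seen. Using only probe sets in the authors' tables was not a separate setting, because all names come from those tables. CYP11B1 and CYP11B2 had no named probe set in H295R.

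Values were log2(intensity + 16), a scale that understates the change of dim genes. H295R arrays were fitted in 1 model with a mean per group (limma 3.58.1, R 4.3.3, lmFit and eBayes), which left 4 residual degrees of freedom. Lone cycloheximide arrays were assumed to vary like the replicated groups. P-values were two-sided and Benjamini-Hochberg adjusted over 11126 genes, with a threshold of 0.05. With 3 against 3 arrays, an exact two-sided permutation test could not go below 0.1. Lists with 5 or more measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Bovine and rat arrays were not tested: genes at or above the median level were counted at 2-fold, and list medians were ranked among 10000 random lists matched on level in 20 bins. Overlaps used one-sided Fisher's exact tests. Gene names and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

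The fit was tested on simulated data for the 11126 genes with 200 changed. For AngII against Basal it recovered 6% of genes changed by 1 on the log2 scale, 84% by 2, 94% by 3 and 98% by 4. For the lone cycloheximide arrays it recovered 0%, 8%, 60% and 80%. Simulated unchanged genes gave 10 and 4 calls. The simulated noise was independent between arrays, without the array sets described below. Recovery in the real arrays can thus be lower than these shares: TRIB1, with a log2 difference of 3.28 for AngII against Basal, did not pass.

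The 20 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 15 largest rises and 8 largest falls past the threshold with separated arrays, up to 4 members of each list past the threshold, and in bovine and rat the 12 largest rises and 6 largest falls at or above the median level with list members at 2-fold. It also took STAR, CYP11B2, CYP11B1, HSD3B2, CYP17A1, AGTR1, NR4A1, NR4A2, NR4A3, FOS, EGR1, ATF3 and JUN. A gene that this rule takes is not reported here. List members that passed only when adjusted over the list alone were named beyond that rule, after their values were seen. Array sets were separated at an actin 3' to 5' ratio of 10, after the data were seen. Alternatives covered scaling, quantile normalization, filters, probe set averaging, moderation, blocks, fold and p thresholds, pseudocounts and leaving out each array.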

Results

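Transcript levels were measured with Affymetrix arrays in adrenocortical cells of 3 species after 1 h with or without 10 nM angiotensin II (AngII), the peptide hormone that drives aldosterone production. H295R, a human adrenocortical carcinoma cell line, had 3 AngII arrays and 3 untreated (Basal) arrays. It also had 1 array with AngII and 35 uM cycloheximide and 1 with cycloheximide alone, a blocker of protein synthesis added 15 min before AngII. Primary glomerulosa cells, which form the aldosterone-producing outer zone of the adrenal cortex, had 1 AngII and 1 control array from cattle and likewise 1 of each from rats. The human arrays held 54613 probe sets other than controls, the bovine 24016 and the rat 31042. The labels do not say whether the H295R replicates were separate cultures, so p-values measure only the spread between these arrays. The number of arrays limits the precision of every value.

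The H295R arrays fell into 2 technical sets. The ratio of the 3' to the 5' actin control probe sets, which rises when labelled RNA is short, was 1.75 for Basal 1, 2.24 for AngII 1, 1.57 for AngII with cycloheximide and 1.64 for cycloheximide. It was 22.4 for Basal 2, 17.5 for Basal 3, 20.0 for AngII 2 and 27.1 for AngII 3. Set 1 thus held replicate 1 of both groups and both cycloheximide arrays, and set 2 held replicates 2 and 3. Median intensity was 77.9 on Basal 2 and between 35.3 and 53.6 on the other 7 H295R arrays. Over the probe sets in the authors' table alone it was 198 on Basal 2 and between 187 and 214 on the others.

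The first comparison asked which genes responded within 1 h in H295R cells. Of 11126 genes tested, 10 rose with AngII and 0 fell (limma, adjusted p below 0.05). They included all 3 members of the NR4A family of orphan nuclear receptors: NR4A2 was 16.4-fold higher (log2 difference 4.04 ± 0.26 SE, n = 3 and 3, limma adjusted p = 0.00118), NR4A3 13.1-fold and NR4A1 5.66-fold. The AP-1 subunits FOS and FOSB were 20.8-fold and 15.9-fold higher, with limma adjusted p = 0.0214 and 0.0320. FOS was near the floor on Basal 2 and Basal 3, and its log2 difference of 4.38 was 5.56 with a pseudocount of 1 and 3.12 with 64. The zinc finger factor EGR1 was 9.53-fold higher, the matrix-associated signalling protein CCN1 8.14-fold, the MAP kinase phosphatase DUSP1 7.39-fold and the ADP-ribosyltransferase TIPARP 4.97-fold. In each of these genes every AngII array lay above every Basal array. On their least raised probe sets NR4A3 was 4.51-fold, EGR1 5.01-fold and CCN1 5.28-fold higher.

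ZEB1, a zinc finger repressor, was the remaining call at 5.67-fold (limma adjusted p = 0.0214), but its probe sets disagreed. The probe set used rose by 2.50 on the log2 scale, whereas the other ZEB1 probe set differed by 0.10, so the gene behind the rise is uncertain. No gene fell past the threshold, and 7 were lower at an unadjusted p under 0.05 against 89 higher, or 30 against 141 with the array set as a block. Chance alone gives 5% of the 11126 genes over both directions if the arrays vary independently, which is more than these counts. Both groups spanned the array sets, which can lower that share. The counts thus cannot decide whether more genes changed. Every AngII array lay above every Basal array for 283 genes, or 2.54%, and below for 117. Chance gives 5% in one direction if every order of the arrays is equally likely, which the array sets make doubtful.

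**Figure D1:**
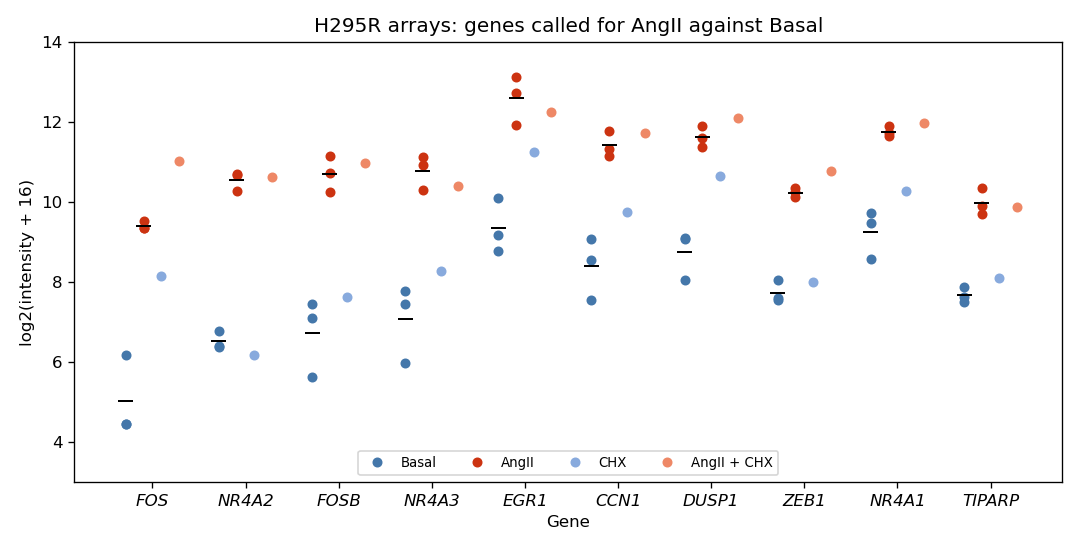
Each point is 1 H295R array, plotted as log2(intensity + 16) for the 10 genes called for AngII against Basal, with black bars for the means of the 3 Basal and the 3 AngII arrays; cycloheximide (CHX) groups have 1 array each. FOS averaged 5.03 in Basal and 9.41 with AngII, and NR4A2 6.52 and 10.56.

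The size of the rise differed between the array sets while its direction did not. Over the 10 genes the median log2 difference was 2.40 in set 1 and 3.69 in set 2, and all 10 were at least 2-fold higher within set 1. EGR1 differed by 1.83 in set 1 and 3.96 in set 2, FOS by 3.33 and 4.90, NR4A2 by 3.90 and 4.11, whereas ZEB1 differed by 2.74 in set 1 and 2.39 in set 2. With the array set as a block, 5 genes passed, 4 of them among the 10 (limma), and set 2 alone gave 4 calls. The call count depended on single arrays: 1 gene passed without AngII 1, AngII 2, AngII 3 or Basal 3, and 16 passed without Basal 1. NR4A2 passed in all 18 alternative settings that measured it, and the other 9 genes in 6 to 9 settings, with every log2 difference of the 10 at 1.30 or above.

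Gene lists fixed before the data were examined held 9 of these 10 genes, and ZEB1 was in none of them. Of 10 measured AP-1 genes, 2 rose over all genes tested and 6 adjusted over the list alone, among them JUNB (log2 difference 2.54), MAFF (1.69), JUN (1.54) and ATF3 (1.15), which did not pass over all genes. The other ATF3 probe set differed by -0.0469, and those of JUN by 1.58 and 0.49. JUNB differed by 1.83 without Basal 2. Of 10 EGR and KLF zinc finger factors, 1 rose over all genes and 7 adjusted over the list alone, with EGR2 at 2.65 (1.87 with a pseudocount of 64) and KLF4 at 2.05. Of 19 immediate-early targets, 4 rose over all genes and 9 adjusted over the list alone, with TRIB1 at 3.28 (3.93 without Basal 1) and GEM at 2.04. Of 13 nuclear receptors, 3 rose by either count, all of the NR4A family. These lists stood above other genes in camera with a preset correlation and kept adjusted p = 0.0114, 0.0114, 0.0114 and 0.0242 with an estimated correlation.

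Feedback genes were also placed high. Of 15 MAP kinase phosphatases and receptor feedback inhibitors, 1 rose over all genes and 3 adjusted over the list alone: DUSP1, SPRY2 (1.86) and RGS2 (1.02). Of 21 genes of mRNA decay, growth arrest and NF-kB feedback, 0 rose over all genes and 6 adjusted over the list alone, with NFKBIZ at 2.50, BTG2 at 2.34 and SOCS3 at 2.32 (2.98 and 1.46 with pseudocounts of 1 and 64). Both lists passed camera, with adjusted p = 0.0206 and 0.0114 with an estimated correlation. The cAMP and calcium feedback list (2 of 19 adjusted over the list alone, NFIL3 and CITED2) and the secreted factor list (1 of 7, CXCL2) lost their camera calls, with adjusted p = 0.164 and 0.178 with an estimated correlation. Both also lost them without Basal 3 (adjusted p = 0.0903 and 0.0886), and the first without AngII 1 (0.118). Ribosomal protein genes were placed low with the preset correlation, median log2 difference -0.08, and lost the call with adjusted p = 0.843 with an estimated correlation. Their direction reversed without AngII 1 (adjusted p = 0.00611, upward) or Basal 3, and the call was lost without Basal 2 (0.186).

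Genes of steroid production showed no call at 1 h. STAR, which moves cholesterol into mitochondria, differed by 0.22 ± 0.36 (SE), HSD3B2 by -0.25, CYP17A1 by 0.07 and the AngII receptor gene AGTR1 by 0.26, with limma adjusted p = 1.00 for each. The sign flipped for STAR, HSD3B2 and CYP17A1 without Basal 2, and for CYP17A1 also under quantile normalization. None of the 16 steroid synthesis, 25 cholesterol, 11 AngII and potassium signalling, 12 clock, 23 stress, 16 reference, 12 zone marker or 5 fibroblast genes passed by either count, and camera called 0 of these lists over all 6 arrays. The cholesterol list was called upward with the array set as a block (adjusted p = 0.0407), with the replicate number as a block (0.0471), without AngII 1 (0.000689) and without Basal 3 (0.0195), against 0.139 over all 6 arrays and adjusted p = 0.769 with an estimated correlation. The reference list was called downward without AngII 2 (adjusted p = 0.0135). Chromaffin, endothelial and immune marker lists had 3, 1 and 3 measured members, too few for a list test, and no member passed.

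The cycloheximide arrays asked which rises occurred when protein synthesis was blocked. All 10 AngII-raised genes were at least 2-fold higher with AngII and cycloheximide than with cycloheximide alone, as were 54 of the other 11116 genes. The log2 difference was 4.45 for NR4A2, 3.35 for FOSB, 2.88 for FOS, 2.75 for ZEB1, 2.14 for NR4A3, 1.96 for CCN1, 1.76 for TIPARP, 1.70 for NR4A1, 1.46 for DUSP1 and 1.01 for EGR1. These 10 genes were at least 4.97-fold higher without cycloheximide. A wider group of 49 genes rose 2-fold or more with every AngII array above every Basal array. Of those 49, 28 were at 2-fold with cycloheximide and 48 were higher. Each arm had 1 array, so the test took its spread from the replicated groups: NR4A2 alone passed (limma adjusted p = 0.0499). That spread spanned both array sets, whereas both cycloheximide arrays lay in set 1, so a failure to pass does not show a weak rise. The NR4A2 call was lost when arrays were centred on their medians, under quantile normalization and with probe sets averaged, all with 0 calls.

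The difference between the AngII effects with and without cycloheximide was tested directly and gave 0 calls (limma; 6 genes higher and 3 lower at an unadjusted p under 0.05). With the array set as a block it again gave 0 calls (limma; 21 higher and 17 lower at an unadjusted p under 0.05). Over the 10 genes the median AngII difference was 2.05 with cycloheximide, 3.14 over all arrays without it and 2.40 within set 1, which held both cycloheximide arrays. The 10 genes were chosen on the arrays without cycloheximide, which by itself favours larger differences there. Cycloheximide against Basal gave 0 calls (limma; 43 genes higher and 34 lower at an unadjusted p under 0.05). The array set entered that comparison: with it as a block there were 0 calls (limma; 23 higher and 24 lower at an unadjusted p under 0.05), and genes at 2-fold went from 260 higher and 140 lower to 14 and 15. Without Basal 1 there was 1 call, in a comparison of a set 1 array with set 2 arrays alone, where set and cycloheximide cannot be told apart. Within set 1, cycloheximide alone differed from Basal 1 by a median of 0.51 over the 10 AngII-raised genes on the log2 scale, without a replicate check. Of 39 genes of the AP-1, EGR and KLF, and immediate-early lists, 5 were at 2-fold: JUN at 2.13, FOS at 1.97, DUSP1 at 1.55, KLF6 at 1.27 and EGR1 at 1.14. Of the 39, 34 were higher than in Basal 1, ID1 at 0.98, MYC at 0.74 and FOSB at 0.19 among them. JUNB at -0.0112 and KLF5 at -0.17 were among the lower ones, and NR4A2 of the nuclear receptor list differed by -0.19. Basal 1 had also entered the test by which FOS, DUSP1 and EGR1 were called. KLF6, KLF5, ID1 and MYC were chosen after their values were seen.

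In bovine glomerulosa cells AngII was compared with control on 1 array each, without a replicate check or test. The median gene differed by -0.30 on the log2 scale, and changes are given relative to that shift. NR4A2 was 9.52-fold higher, FOS 7.49-fold, the coagulation initiator F3 4.72-fold, DUSP1 4.66-fold, STAR 3.99-fold, JUNB 3.03-fold, NR4A1 2.88-fold and EGR1 2.81-fold. STAR probe sets disagreed: the dimmer one, below the median level, was at 0.914-fold, so the STAR value is uncertain. The dimmer FOS probe set was 3.82-fold higher. NFIL3, PLK2 and TCIM were 2.71-fold, 2.61-fold and 2.59-fold higher, and a probe set described as similar to CHD3 was 6.63-fold higher against 1.14-fold for the other CHD3 probe set. Below the median level, NR4A3 was 20.7-fold, RGS2 3.08-fold and FOSB 3.01-fold higher. Lower were MX2 (log2 difference -1.74), CTNND1 (-1.21), TREX1 (-0.84), IBSP (-0.83) and YWHAZ (-0.80). Among 1838 genes at or above the median level, 12 were at least 2-fold higher and 11 lower as deposited, against 13 and 2 relative to the shift.

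In rat glomerulosa cells the median shift was -0.08. Relative to it, NR4A3 was 9.90-fold higher, FOS 4.52-fold, EGR1 3.69-fold, GEM 3.02-fold, ATF3 2.91-fold and CYP21A1, a steroid 21-hydroxylase gene, 2.62-fold. NFKBIA, HSPA1B, DUSP6, IER2, SPRY2 and RGS2 lay between 1.96-fold and 2.18-fold, and a dimmer RGS2 probe set was 3.07-fold higher. Below the median level EGR3 was 20.3-fold, FOSB 17.1-fold, NR4A1 13.5-fold, NR4A2 3.68-fold and BTG2 3.26-fold higher (5.09-fold on the other BTG2 probe set). Lower were MMP12 (-1.66), ARL6IP5 (-1.39), CCL2 (-1.20), ITGB2 (-1.15), SPN (-1.06) and HMGCS1 (-0.87). STAR differed by 0.26, JUN by 0.08 and AGTR1 by -0.04. Among 2810 genes at or above the median level, 8 were at least 2-fold higher and 5 lower as deposited, against 11 and 5 relative to the shift.

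The fixed lists were ranked among random lists in each species, without a test between species. The AP-1 list had a median of 0.81 in bovine and 0.75 in rat cells relative to the shift, each at percentile 100 among 10000 random lists matched on level. The immediate-early target list had medians of 0.44 and 0.32, again at percentile 100 in both. Nuclear receptors stood at percentile 98.9 and 100 after rounding, with NR4A1, NR4A2 and NR4A3 as the 3 members at 2-fold. EGR and KLF factors stood at percentile 100 in rat cells, and the 4 measured in bovine cells were too few to rank. Ribosomal protein genes stood at percentile 99.2 and 97.9, with medians of 0.12 and 0.0968 and 0 members at 2-fold. The steroid synthesis list stood at percentile 99.7 in bovine cells, where STAR was the 1 member at 2-fold, and at 96.1 in rat cells. The bovine percentile was 97.49 with the other STAR probe set and 96.0 without STAR. Among markers of other adrenal cells, the bovine lists stood at percentile 8.18 for chromaffin cells, 92.6 for endothelium, 16.5 for fibroblasts and 91.4 for immune cells. The rat lists stood at 93.6, 17.0 and 81.0 for chromaffin, fibroblast and immune markers, and 4 endothelial genes had a median of 0.50.

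Across species, 941 genes were measured on all 3 platforms at or above the median level in bovine and rat. FOS and EGR1 were raised in all 3, where independent lists would share 8.13e-05 genes. H295R and bovine shared 3 raised genes (one-sided Fisher's exact p = 5.77e-07), H295R and rat 2 (exact p = 4.06e-05), and bovine and rat 2 (exact p = 0.000101). Genes are not independent replicates, and bovine and rat had 1 array per group, so these p-values do not measure replication of the AngII effect. The level was the mean of the control and AngII arrays, so a rise helped a gene enter. Bovine FOS was 8.38 in control, below the median level of 8.95, and 10.98 with AngII. Without the filter on level the shared genes numbered 6: EGR1, FOS, FOSB, NR4A1, NR4A2 and NR4A3. The count with the filter was 1 with arrays centred on their medians, 1 under quantile normalization and 0 with probe sets averaged. Of the 10 H295R genes, 7 of 8 measured were at least 2-fold higher in bovine cells and 6 of 10 in rat cells, and the list's median lay at percentile 100 in both. TIPARP was 1.60-fold higher in bovine and 1.18-fold in rat cells relative to the shift, and DUSP1 1.10-fold in rat cells.

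**Figure D2:**
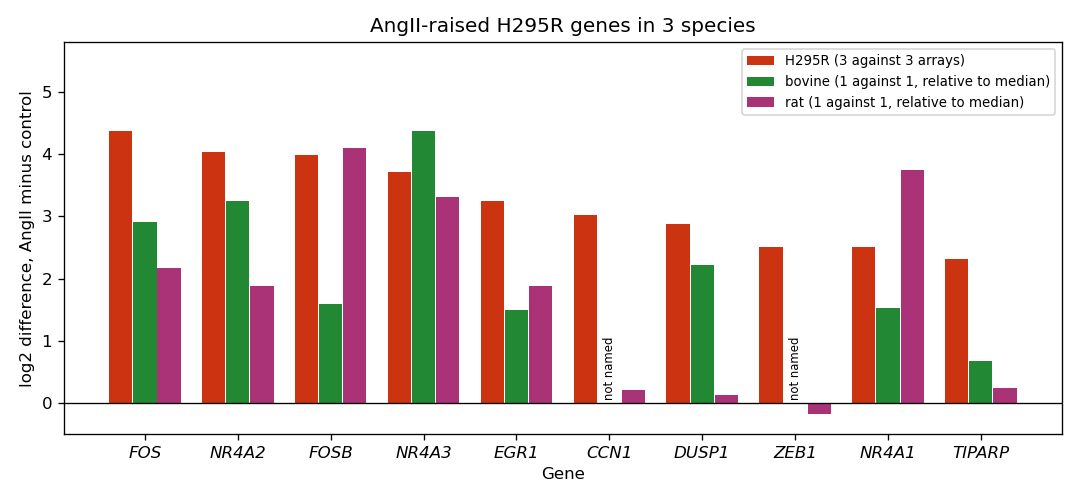
Bars give the log2 difference of AngII minus control for the 10 genes called in H295R, with H295R from 3 against 3 arrays, and bovine and rat from 1 against 1 array relative to the median gene; bars start at 0 and no error is drawn. NR4A3 reached 3.71 in H295R, 4.37 in bovine and 3.31 in rat cells, whereas ZEB1 reached 2.50 in H295R and -0.18 in rat cells. The H295R value of ZEB1 rests on 1 probe set, and its other probe set differed by 0.10.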

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

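The tests of array set, of the level reached with AngII and cycloheximide, of untreated cultures and of cycloheximide on the fixed lists were chosen after the result was seen, as was the count of splits.

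Some probe sets without a gene name also stood higher with AngII. At or above the median level, 10 of 2850 in bovine and 5 of 2039 in rat cells were at 2-fold or more relative to the median gene. The highest were at 2.75-fold and 4.18-fold. Among named genes the counts were 13 of 1838 and 11 of 2810.

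Some genes with every H295R AngII array above every Basal array did not stand above the median gene in another species, and the difference was not tested. How many of all such genes did so was not counted. CXCL2 at -0.0500 and SGK1 at -0.0859 lay close to the median gene in bovine cells, and STC1 differed by -0.83. In rat cells STC1 differed by -0.23 and ZEB1 by -0.18. STC1 did not pass in H295R over its list alone (limma adjusted p = 0.0547), and its bovine level of 7.27 was below the median level of 8.95. The ZEB1 rise in H295R rests on 1 probe set, and its other probe set differed by 0.10, so that contrast may compare different genes.

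The AngII against Basal fit called 10 genes, and the highest count among the other splits of the 6 arrays was 0. Only 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

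The AngII differences of 9 of the 10 raised genes were larger in set 2 than in set 1, with a median gap over the 10 of 1.03 on the log2 scale. ZEB1 went the other way, with 2.39 in set 2 and 2.74 in set 1. Basal levels of these genes were lower in set 2 (median -0.86) and AngII levels higher (0.39). With a pseudocount of 64 a gap of 0.83 ± 0.27 remained, above the bound set in advance. Here ± is the standard error of the median over the 10 genes and leaves out the spread between arrays. Set 1 held 1 array of each group, so low Basal values near the floor stay open as a cause. A wider spread of values on the set 2 arrays stays open: quantile normalization left 0.69 ± 0.32, too uncertain to place against the bound set in advance. No biological explanation was tested.

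The AngII differences were also smaller with cycloheximide, by a median of 0.93 against all arrays, although those of NR4A2 and ZEB1 were larger. Against set 1 alone the shortfall was 0.31 ± 0.19, with ± again over the genes and not over arrays. The array set may thus account for much of it, and that spread keeps the question open. The raised genes were also chosen for large differences on the arrays without cycloheximide, AngII 1 and Basal 1 among them. That choice by itself favours a shortfall against either reference. A lower level reached with AngII also stays open: the array with AngII and cycloheximide exceeded AngII 1 by a median of 0.38, but each is 1 array, and AngII 2, of the other set, exceeded AngII 1 by 0.49 in these genes. A raised baseline with cycloheximide remains possible and rests on 1 array.

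Over the AP-1, EGR and KLF, and immediate-early lists pooled, 34 of 39 genes were higher with cycloheximide alone than in Basal 1, with a median of 0.34 at percentile 100 of random lists. A candidate explanation is that cycloheximide by itself raises such transcripts. The percentile was also 100 after quantile normalization. Random lists matched on level move with most scaling differences too, so that result could hardly have changed and does not decide on scaling. The lists did stand above genes of similar level. Variation between untreated cultures or their arrays stays open, because set 1 held a single Basal array. Basal 1 differed in the same lists from Basal 2 by a median of 0.67 and from Basal 3 by 0.25, which both include the array-set difference, while Basal 2 and Basal 3, of set 2, differed by 0.20.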

How the results depend on the processing

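The batch block, pseudocounts, set 2 alone, scaling over named genes, other probe sets and names from symbols alone were chosen after seeing the data. Among alternative counts and percentiles, 106 stayed within 1.5 times their main value or on their side, and 60 moved. The cause was not tested except where fewer arrays or genes entered. AngII against Basal gave 10 genes as planned, 2 with each array centred on its median over all probe sets (8 over named genes), 5 under quantile normalization (4 over named genes), 6 with averaged probe sets, 1 with every probe set by itself, 5 with the batch block, 4 in set 2 alone, 1 at adjusted p below 0.01 and 1 with pseudocount 1. Leaving out 1 array gave 1 to 16 genes. Genes kept under cycloheximide numbered 10 of 10 called, then all of the called 2, 5, 4, 6, 1, 5 and 1 under centring, quantile normalization, that over named genes, averaging, single probe sets, the batch block and pseudocount 1, and 1 to 15 with 1 array left out, which was every called gene except for 15 of 16 without Basal 1. They also numbered 13 of 14 with only genes at or above the median level and 11 of 12 with pseudocount 64. The cycloheximide test of AngII gave 1 gene and 0 under both centrings, both quantile normalizations, averaging, single probe sets, the replicate block and pseudocount 1, and 0 to 1 with 1 array left out. Cycloheximide against Basal gave 0 genes, and 0 to 1 with 1 array left out, the 1 without Basal 1, which leaves only set 2 Basal arrays.

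The replicate block gave 1 gene for AngII against Basal, which was kept. Same-numbered arrays correlated at 0.74, -0.12 and -0.11 in their deviations, whereas AngII 2 correlated with Basal 3 at 0.59 and AngII 3 with Basal 2 at 0.62. Not every array thus correlated best with its own number, and the numbers were not taken to pair the arrays. Each list count stayed within 1.5 times of 9.

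Bovine genes lower numbered 11, then 2 under centring and 2 under quantile normalization, 47 without the filter, 20 with averaged probe sets, 129 at 1.5-fold and 1 at 3-fold, where 6 were higher and 4 of the H295R genes passed. Rat genes gave 21 higher and 24 lower without the filter, 27 and 56 at 1.5-fold, and 3 and 1 at 3-fold. Genes raised in all 3 species numbered 2, then 1 under centring, 1 under quantile normalization, 6 without the filter, 0 with averaged probe sets and 1 at 3-fold. CYP17A1 turned to -0.0267 under quantile normalization and -0.0302 when that ran over named genes. With 1 array left out CYP17A1 ranged from -0.18 to 0.22, STAR from -0.00551 to 0.54 and HSD3B2 from -0.59 to 0.0825. The ribosomal list's adjusted p ranged from 3.22e-10 to 0.45 and its direction reversed without AngII 1 or Basal 3. Intensity near background limits dim genes.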

Other observations

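NFIL3 and PLK2, both among the largest bovine rises, had log2 AngII differences of 2.11 and 1.53 in H295R, and of 1.51 and 1.19 with cycloheximide. Neither passed in H295R over all genes (limma adjusted p = 0.119 and 1.00). STAR was 3.99-fold higher in bovine cells relative to the median gene, 1.16-fold in H295R and 1.19-fold in rat cells, with no test of the difference. The other bovine STAR probe set was at 0.914-fold, so the contrast rests on 1 probe set. RGS2, a regulator of G protein signalling, was 3.08-fold higher in bovine and 1.96-fold in rat cells (3.07-fold on a dimmer rat probe set), and its log2 difference in H295R was 1.02 (limma adjusted p = 0.984).

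Across genes, which are not independent replicates, AngII differences in H295R and bovine cells correlated at 0.30 over 2995 genes and at 0.10 without the AngII-raised genes. For H295R and rat the values were 0.22 over 4475 genes and 0.08.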
